A study of Homo sapiens with 4 samples.

How the data were processed

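Gene expression was measured in 4 samples of cultured cells, Panc-1ER and Panc-1GLI1ER at 0 h and after 3 h with 10 nM E2, with 1 sample and 1 array in each of the 4 groups. Groups, dose and time were taken from the sample titles. Per the labels' protocols, cells were kept in medium with charcoal-treated serum and Cy3-labelled cRNA was made from total RNA for one-colour hybridisation to Agilent 4x44 arrays. Per the submitters' processing notes, the arrays were read with Agilent Feature Extraction 9.1.3.1. Per the file headers, the deposited intensity of each spot (the processed signal) had been background-subtracted and detrended within its array, with a surrogate value where a spot did not exceed background, and no scaling between arrays is recorded. The authors' deposited value table also holds an intensity per probe. It was set against the scanner values and equals the processed signal divided by the array's median, on a linear scale without centring of genes, since 100% of 40997 probes on each array matched within 5% and each column's median was 1; how the authors made that table is not given in the sources used here. The barcodes place both Panc-1ER arrays on 1 slide and both Panc-1GLI1ER arrays on another, each with its own scan, so slide was not fitted as a block.

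Control spots were left out, as were spots that the software had marked as non-uniform or population outliers (3 in Panc-1ER at 0 h and 1 in Panc-1GLI1ER at 0 h), with which 3 probes were lost. Spots of 1 probe were averaged on the log2 scale. Of 264 probes with 10 spots, 204 to 210 were well above background, and the median SD between their spots was 0.07 log2 in both Panc-1ER arrays, 0.09 in Panc-1GLI1ER at 0 h and 0.08 in Panc-1GLI1ER with E2. No probe was saturated. The main values are log2 of the processed signal minus the array's 75th percentile over all probes, and scaled signals in the text are these values on a linear scale multiplied by 1106, the geometric mean of the 4 percentiles. A probe counted as well above background on an array where the scanner software had marked a share of at least 0.5 of its spots so. This held for 24503, 23640, 23654 and 23944 probes in Panc-1ER at 0 h and with E2 and in Panc-1GLI1ER at 0 h and with E2.

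The scanner files name probes by accession. RefSeq accessions, compared without their versions, were paired with symbols through a RefSeq gene table (assembly GRCh38.p14), used for names only; the files do not name a genome build and no coordinates are given. Of 41000 probes, 22769 (55.5%) matched 1 symbol, none matched several and 18231 matched none, and the last were kept out of gene counts. The 16059 named genes were each read from the probe with the highest mean log2 signal over the arrays; 5342 genes had more than 1 probe, and in 18 genes the chosen probe was below background everywhere while another was above it on at least 1 array.

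A change is the difference of log2 values of 2 single arrays, or the difference of both lines' E2 responses over all 4 arrays. Each group holds 1 array, so no comparison made here has replicates, and changes are described by size and not tested. A change was counted at 2-fold or more (log2 of 1). Where a probe was well above background on 1 side only, the change was given as a lower bound ("at least"), as the bright value over the higher of the dim value and the lowest signal of any gene well above background on the dim array (35.2, 39.4, 40.7 and 39.0 in the order above); where it was dim on both sides no fold is given. The error of a change combines the scanner software's error model of the signals and covers neither culture nor labelling. For gene lists, the median of the measured members was placed among medians of 10000 random lists of the same size, drawn from 20 bins of mean signal. The 24 lists hold 631 entries, of which 603 matched a gene on the arrays. Of the 49 GLI targets on the arrays, 19 also stand in another list, such as ARC among immediate early genes and KRT17 among pancreatic duct genes.

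The rule for naming genes, like the lists, the comparisons and the alternatives below, was fixed before the data were examined. It takes the 15 largest increases and 10 largest decreases of the Panc-1GLI1ER response, its 5 largest lower bounds in each direction, the 8 largest changes in each direction in Panc-1ER, the 10 largest in each direction of the difference of responses and of the 0 h comparison, GLI1, ESR1, PTCH1, HHIP, MUC5AC, SNAI1 and CDH1, all GLI targets at 2-fold in a response, and up to 4 members per list with the largest response in Panc-1GLI1ER; some genes that the rule takes are left out of the text. ELF3, CXCR4, TXNIP, ARRDC4, CXCL2, FOSB, ID3, IGFBP6, IL1R2, ABCG2, CDH2, FN1, SNAI2, MMP2, MMP7, MMP9, COL3A1, EGR4 and the further genes named in the closing section were added after their values had been seen.

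The alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, scaling to the median, cyclic loess, scaling to 7 spike-in probes with a signal over 100 on each array, the deposited value table, genes well above background on all 4 arrays only, no filter, the mean over all probes of a gene, and a 1.5-fold limit. Normalizations were run in R 4.3.3 with limma 3.58.1, and other steps in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated arrays made from the real mean signals and the software's errors, with 200 genes changed. For the Panc-1GLI1ER response over 11031 genes, 98% of 50 genes changed 3-fold, 60% of 50 changed 2-fold and 6% of 50 changed 1.5-fold passed the 2-fold limit, none with the wrong sign, and 1 unchanged gene passed. For the difference of responses over 10828 genes the shares were 92%, 62% and 14%, and 31 unchanged genes passed. The simulated errors of a difference were larger than the spread of the real differences. A simulated list of 20 genes shifted by 0.3 log2 had a percentile of 99.99 and an unshifted list 58.2.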

Results

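In order to identify genes that respond to the transcription factor GLI1, expression profiles were recorded in derivatives of Panc-1, an established human pancreatic ductal adenocarcinoma cell line. GLI1 is the zinc finger activator at the end of the Hedgehog pathway. Per its name and the study's title, the Panc-1GLI1ER line carries GLI1 joined to a part of the estrogen receptor, so that beta-estradiol (E2) switches the fusion protein on, and Panc-1ER serves as its control line. Each of the 2 lines was profiled at 0 h and 3 h after addition of 10 nM E2. The data were 4 one-colour Agilent arrays with 41000 probes each, 1 array per group. There were no replicates, so no difference below has a replicate check, no test was run and no p-value is given. The number of arrays limits the precision, and the error given beside a value is the scanner software's own technical error of the signals (SD on the log2 scale). Of the probes, 59.8% were well above background in Panc-1ER at 0 h, 57.7% in Panc-1ER with E2, 57.7% in Panc-1GLI1ER at 0 h and 58.4% in Panc-1GLI1ER with E2. In what follows a gene "rose" or "fell" where its change was 2-fold or more, and a gene list did so where its median lay outside the central 95% of 10000 random lists of the same size and signal. Percentiles of lists describe these arrays only.

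GLI1 itself (NM_005269) was measured well above background on every array. Its scaled signal was 71.5 in Panc-1ER at 0 h, 117 in Panc-1ER with E2, 1203 in Panc-1GLI1ER at 0 h and 1865 in Panc-1GLI1ER with E2. GLI1 was therefore 16.8-fold higher in Panc-1GLI1ER before E2 (log2 4.07, error 0.26) and 16.0-fold higher at 3 h. The E2 response of the probe was a log2 change of 0.63 in Panc-1GLI1ER and 0.70 in Panc-1ER, below the 2-fold limit in both. The array holds 1 GLI1 probe, and its signal was not divided between the endogenous gene and the fusion. ESR1, the gene of the estrogen receptor, and HHIP, a Hedgehog target that restrains the pathway, were not well above background on any of the 4 arrays.

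**Figure D1:**
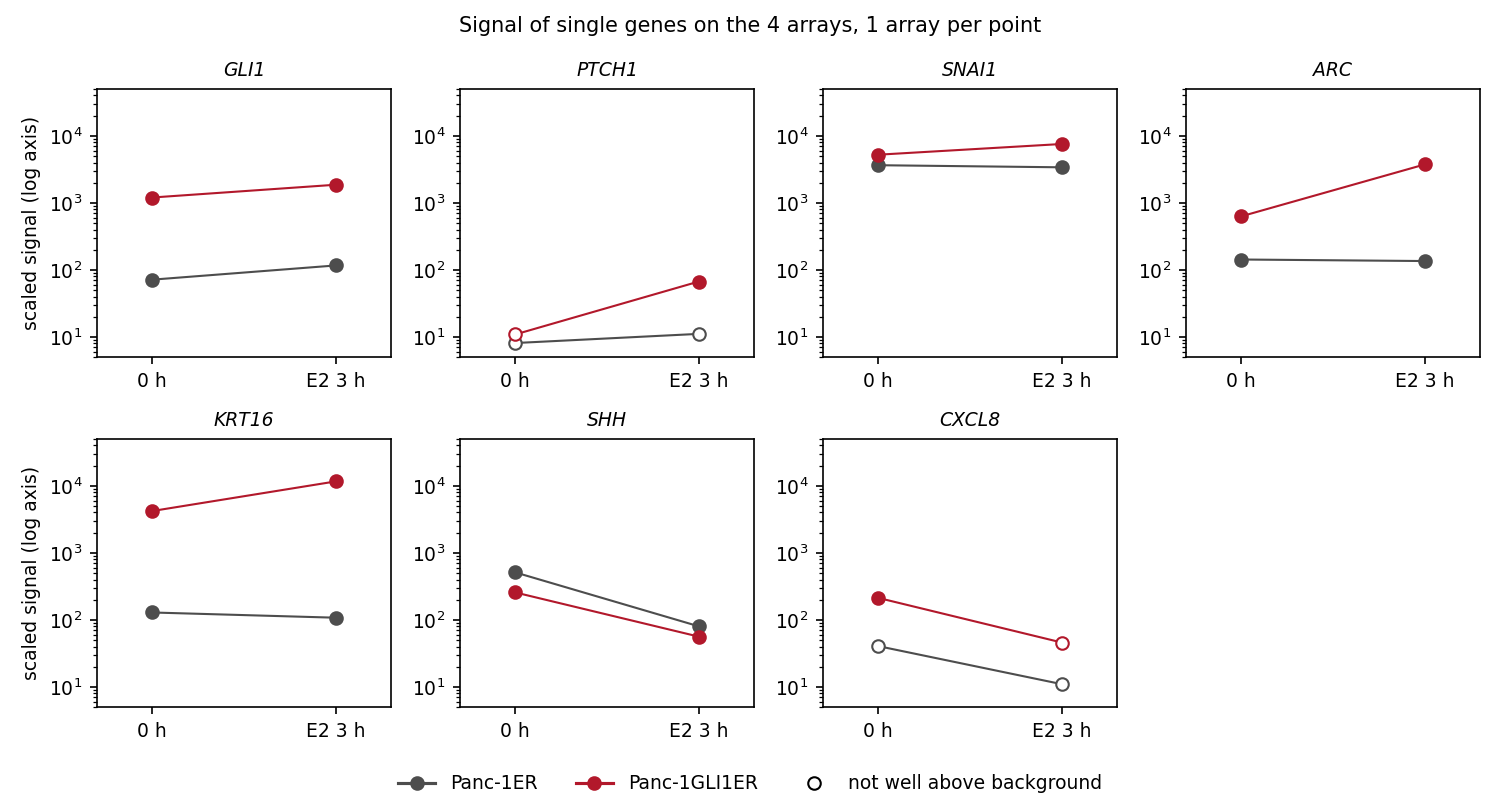
Scaled signal (log axis) of 7 genes on the 4 arrays, with 0 h and E2 at 3 h joined by a line for Panc-1ER (grey) and Panc-1GLI1ER (red); each point is 1 array and open points were not well above background. Compared within each panel, GLI1 went from 1203 to 1865 in Panc-1GLI1ER and from 71.5 to 117 in Panc-1ER, and ARC from 630 to 3743 and from 143 to 136.

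The first comparison asked which transcripts change within 3 h of E2 in the line that carries the GLI1 fusion. ARC, a neuronal immediate early gene, rose most among genes measured on both arrays, by 5.95-fold (log2 2.57, error 0.21). It was followed by NOVA2, an RNA-binding splicing regulator (3.50-fold), RASD1, a small GTPase induced by glucocorticoids (3.33-fold), and DEPP1, a FOXO-responsive gene (3.24-fold). KRT16, a keratin of stressed epidermis, rose 2.77-fold, DDIT4, a stress-induced inhibitor of mTORC1 signalling, 2.58-fold, and EDN2, a vasoactive peptide, 2.57-fold. GSC, a homeobox gene (2.64-fold), MNX1, a homeobox gene of motor neurons and pancreas (2.60-fold), HSPA6, an inducible heat shock protein (2.65-fold), C2orf15, TM6SF2, CNTRL and ZDHHC11 were also among the 15 largest increases. The largest decreases among such genes were in CCL20, a chemokine (4.78-fold lower), SHH, a Hedgehog ligand (4.56-fold lower), SLC7A4 (4.03-fold lower), CCL7, a further chemokine (3.55-fold lower), C2CD4B, MYORG, KRTAP3-1, BIRC3, an inhibitor of apoptosis induced by NF-kB (3.19-fold lower), ARTN, a ligand of the GDNF family, and LCN1.

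In all, 92 genes rose and 115 fell among 16059 named genes, and 11031 genes were measured on both arrays. Of these, 49 of the higher and 52 of the lower genes were measured on both arrays, and the other 43 and 63 were well above background on 1 array only, so that their change is a lower bound. The largest such bounds were at least 8.42-fold for CCR4, a chemokine receptor, 8.05-fold for TFCP2L1, a Grainyhead-like transcription factor, 5.91-fold for BTN3A3, 5.30-fold for PCDHGB2 and 4.73-fold for SORCS1, all higher. On the lower side NKX6-3, a homeobox gene, fell at least 9.04-fold, PAX1, a paired box gene, at least 7.63-fold and MYL4 at least 7.33-fold, although its other probe had a log2 change of 2.74. The share of higher genes among those counted was 44.4%. It was 24.5% after normexp background correction, which shrinks dim signals, and 35.3% when the arrays were scaled to spike-in RNA, which moved the median of all genes from -0.02 to -0.12 in this response.

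Known GLI targets rose as a list in Panc-1GLI1ER, with a median log2 change of 0.11 over 25 measured members, although without any filter on dim probes the median was -0.01 and inside the random range (percentile 96.9), and it was 0.04 after normexp correction and 0.01 with spike-in scaling. The 0.11 was higher than 99.9% of matched random lists, and 17 of the 25 members were above 0. Single members went both ways. ARC rose, whereas CCND2, a G1 cyclin (at least 3.30-fold), MYCN (2.76-fold) and ZEB1, a repressor of E-cadherin (at least 2.60-fold), fell. PTCH1, the Hedgehog receptor and a classic GLI1 target, was well above background only in Panc-1GLI1ER with E2, where it was at least 1.65-fold higher than at 0 h. The log2 change of SNAI1, a repressor of E-cadherin, was 0.53, while CDH1 (E-cadherin) had 0.05. No probe was paired with MUC5AC, so this mucin is not analysed here. KRT17, an epithelial keratin on the target list, had a log2 change of 0.91.

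Notch pathway genes also rose, with a median of 0.24 over 14 measured members, higher than 99.99% of random lists. Of 20 members on the array, HEYL (2.47-fold), MFNG, a Fringe glycosyltransferase (2.22-fold), and HES5 (at least 2.60-fold) rose, none fell, and LFNG had a log2 change of 0.62. In Panc-1ER the log2 changes were 0.42 for HEYL, 0.83 for MFNG, 0.35 for HES5 and -0.04 for LFNG. The scaled signal of HES5 was 30.1 (dim) and then 106 in Panc-1GLI1ER, against 99.6 and 127 in Panc-1ER, so its rise rests on the low value at 0 h. The TGF-beta and BMP list had a median of 0.13 (99.9th percentile), with no member at 2-fold; SMAD6, an inhibitory SMAD, had 0.65 and BAMBI, a decoy receptor, 0.62. Genes induced by NF-kB fell the most as a list. Their median was -0.49, lower than in any of the 10000 random lists, and 19 of the 22 measured members were below 0. CCL20, BIRC3, CXCL1 (2.33-fold), CXCL2 and CXCL8 (at least 4.63-fold), chemokines apart from BIRC3, fell and none rose. The second probe of CXCL2 moved the same way. Feedback genes of the MAPK pathway fell too, with a median of -0.13 (percentile 0.3), but lay inside the random range without a filter (percentile 11.7). Of this list HBEGF, an EGFR ligand, fell 2.21-fold, and EREG and AREG, ligands of the same receptor, had log2 changes of -0.83 and -0.78. Mitosis genes (median 0.06) and genes of the unfolded protein and amino acid response (0.07, with DDIT4) rose, whereas with spike-in scaling these medians were -0.04 and -0.03, above the -0.12 of all genes. Acinar and islet genes, markers of other pancreatic cells, had a median of -0.26 (percentile 1.24), with 4 measured members only, and percentile 22.7 without a filter. Immediate early genes showed a median of -0.04 inside the random range (percentile 40.0), but below it with the mean over all probes of a gene (percentile 1.08) and with genes above background on all 4 arrays (2.03), although ARC and BTG2, an antiproliferative gene (2.34-fold), rose.

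The second comparison gave the response to E2 in the control line Panc-1ER, the background for every value above. SHH fell 6.37-fold (log2 -2.67, error 0.28), the largest decrease among genes measured on both arrays. ARTN (3.70-fold lower), C2CD4B (3.58-fold lower), SOX18, an endothelial transcription factor (3.41-fold lower), TLX2, a homeobox gene (3.39-fold lower), HRK, a pro-apoptotic BH3-only gene (3.25-fold lower, but log2 -0.20 on its other probe), and GRIN1, an NMDA receptor subunit (3.20-fold lower), fell as well, as did FLRT2, measured in this line only. Genes that rose were PCDHGA2 (5.78-fold), PLAG1, a zinc finger transcription factor (3.37-fold), and CPT1B, a mitochondrial carnitine palmitoyltransferase of muscle (3.24-fold). CNIH3, OR6M1, S100Z, ZDHHC11 and PAX7, a myogenic transcription factor (3.08-fold), rose too. The scaled signals of all these rising genes at 0 h lay between 35.2 (PCDHGA2) and 132 (ZDHHC11).

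A total of 89 genes rose and 109 fell in Panc-1ER, of which 40 and 52 were measured on both arrays. The share of higher genes was 44.9%, against 25% after normexp correction and 71.6% with spike-in scaling, which moved the median of all genes to 0.21. GLI targets had a median of -0.10 here, inside the range of random lists (percentile 3.46), but below it with quantile normalization (percentile 1.11), cyclic loess (1.74) and the mean over probes (2.22), and at 0.09 (percentile 75.1) without a filter. MYCN (2.32-fold lower) was the single member at 2-fold, and with spike-in scaling the median was 0.13, below the 0.21 of all genes. Known estrogen-induced genes had a median of -0.01, also inside the random range. NF-kB-induced genes fell in this line as well, with a median of -0.47, lower than all random lists, and CXCL1 fell 2.12-fold. MAPK feedback genes (median -0.25) and immediate early genes (median -0.28) lay below all random lists too, with EGR4, a zinc finger transcription factor, at -1.50. The median of TGF-beta and BMP genes was -0.16 (percentile 0.15) but 0.07, still below the 0.21 of all genes, with spike-in scaling. Wnt genes had -0.22 (percentile 0.01, but inside the random range at 18.8 without a filter and 2.99 with the mean over probes) and adhesion and epithelial-mesenchymal transition genes -0.16 (percentile 0.05), and with spike-in scaling their medians were 0.01 and 0.07, below that of all genes. Genes of the unfolded protein and amino acid response (median 0.15), cholesterol synthesis (0.12), heat shock (0.06) and mitosis (0.05) rose in Panc-1ER.

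**Figure D2:**
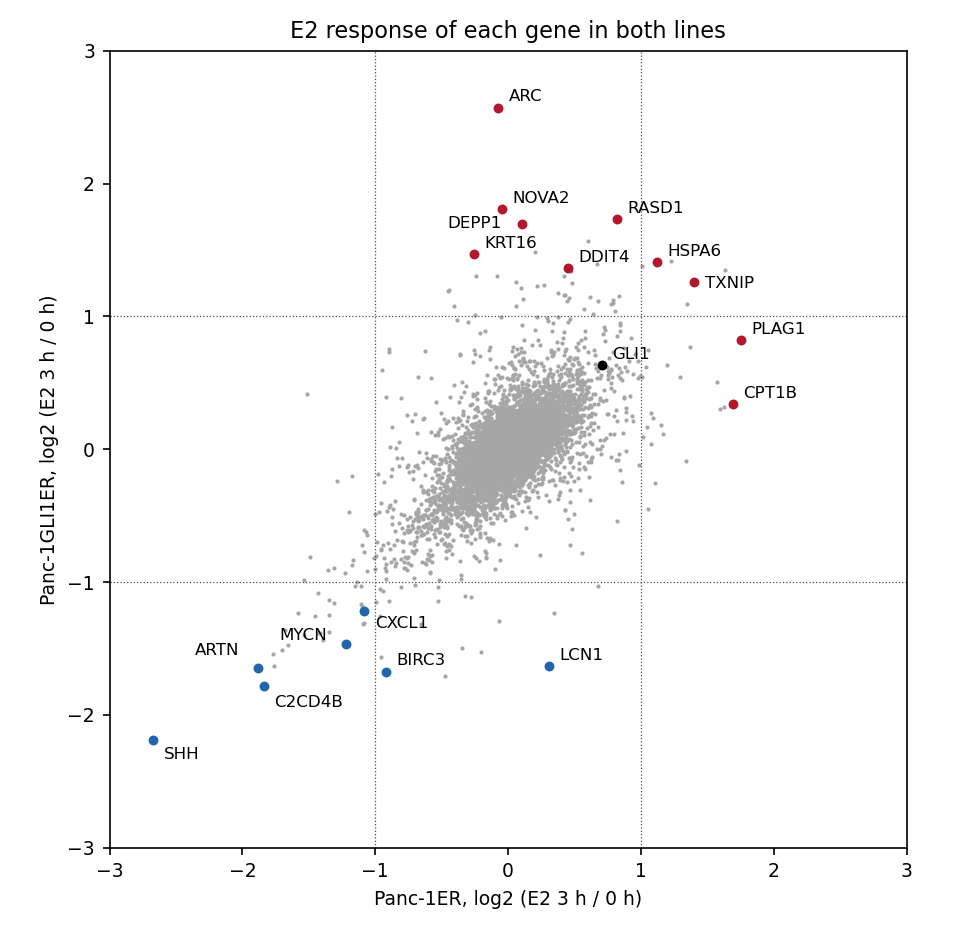
Log2 ratio of E2 at 3 h over 0 h in Panc-1ER (x axis) and in Panc-1GLI1ER (y axis) for the 10828 genes measured on all 4 arrays; dotted lines mark 2-fold changes and 18 genes are labelled (red higher, blue lower in at least 1 line, black neither). Across genes the responses had a Pearson correlation of 0.635, and ARC, at 2.57 in Panc-1GLI1ER and -0.08 in Panc-1ER, lies far from the diagonal.

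Across the 10828 genes measured on all 4 arrays, the responses of both lines had a Pearson correlation of 0.635 and a Spearman correlation of 0.582, while the Pearson correlation was 0.143 without a filter on dim probes; genes are not independent replicates, and the 2 responses share no array. SHH, ARTN, MYCN, CXCL1, SOX18, GRIN1 and TLX2 were among 27 of these genes that fell in both lines, out of 48 in each line. Independent lists of that size would share 0.213. Of the same genes, 6 rose in both lines (44 and 27 in each, 0.11 expected for independent lists), namely TXNIP, an inhibitor of thioredoxin, its relative ARRDC4, HSPA6, MNX1, CNTRL and ZDHHC11. TXNIP rose 2.40-fold in Panc-1GLI1ER and 2.64-fold in Panc-1ER. GSC, dim in Panc-1ER at 0 h and so not among these genes, also rose in Panc-1ER, by at least 2.09-fold. RASD1 went from a scaled signal of 2286 to 4033 in Panc-1ER, short of 2-fold. The 4 samples hold no 3 h culture without E2, so the effect of E2 is not separated from that of 3 h in culture.

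The third comparison set the response of Panc-1GLI1ER against that of Panc-1ER, so that a change in either line can bring a gene up. Among genes measured on all 4 arrays ARC had the largest excess, with a response 6.27-fold higher in Panc-1GLI1ER (log2 difference 2.65, error 0.31). NOVA2 (3.61-fold), KRT16 (3.31-fold) and DEPP1 (3.01-fold) followed the same course, since each had a log2 change between -0.26 and 0.11 in Panc-1ER. DEFB4A, a beta-defensin, fell in Panc-1ER (log2 -1.52) and had 0.41 in Panc-1GLI1ER. COQ8B, RBM11 and SH3BP1 had log2 changes from -0.95 to -0.89 in Panc-1ER and from 0.60 to 0.76 in Panc-1GLI1ER, and the other probe of SH3BP1 had a log2 difference of -0.49. PI3, an elastase inhibitor of epithelia, and YPEL4 rose in Panc-1GLI1ER (2.30-fold and 2.28-fold) and had -0.44 and -0.45 in Panc-1ER. ELF3, an epithelial ETS factor (2.92-fold), and CXCR4, a chemokine receptor (2.39-fold), were picked out after their values had been seen. On the lower side stood LCN1 (3.85-fold lower), KLF17, ZNF569 and CUL3, a ubiquitin ligase scaffold, which fell in Panc-1GLI1ER. CPT1B, HLA-DMA, CD248 and CFAP91 instead rose in Panc-1ER (log2 1.69, 1.34, 1.10 and 1.05) and had 0.34, -0.09, -0.26 and -0.45 in Panc-1GLI1ER, and SPTBN5 and KDM1B passed 2-fold in neither line.

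In total 36 genes had a response at least 2-fold higher and 25 at least 2-fold lower in Panc-1GLI1ER, among 10828 genes. Genes dim on any of the 4 arrays could not enter this count. Of the 92 genes that rose in Panc-1GLI1ER, 32 were dim on both Panc-1ER arrays. At 3 h 31 of these were at least 2-fold higher than in Panc-1ER, a comparison made across slides. Of the 61 counted genes, 48 lay in the lowest of 4 equal signal groups, where errors are largest. In simulated arrays 31 genes left unchanged passed the same limit. The simulated errors were larger than the spread of the real differences, however. The error of a difference was 0.29 even for a bright gene such as EEF1A1. The SD of the real differences, estimated from their median absolute deviation, was 0.15 over all genes and 0.23 in the lowest group. The 31 therefore does not tell how many of the 61 arose by error. With normexp correction 16 were higher and 6 lower, and with spike-in scaling 15 and 75; the share of higher genes was 59.0%, 72.7% and 16.7% in turn, as spike-in scaling moved the median of all genes to -0.33. As a list, GLI targets had a higher response in Panc-1GLI1ER, with a median difference of 0.16 over 23 members, although with spike-in scaling the median was -0.17, above the -0.33 of all genes. The 0.16 lay above all 10000 random lists, and 18 members were above 0, but without a filter the median was 0.01, inside the random range (percentile 90.6). SNAI1 had a log2 difference of 0.63 and SOX9, a progenitor and ductal transcription factor, of 0.55, while GLI1 had -0.07.

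Lists with a higher response in Panc-1GLI1ER were also immediate early genes (median 0.27) and TGF-beta and BMP genes (0.27), both above all random lists, Notch genes (0.19, percentile 99.97) and Wnt genes (0.10, percentile 98.8); with spike-in scaling these medians were -0.06, -0.06, -0.14 and -0.23, each above the -0.33 of all genes, and Wnt genes lay inside the random range with normexp correction (percentile 96.9). Immediate early and Wnt genes did not rise as lists in Panc-1GLI1ER (median -0.04 for each) but were lower in Panc-1ER (-0.28 and -0.22). ARC, BTG2 and FOSB, an AP-1 subunit, passed 2-fold among immediate early genes and ID3, a BMP-induced repressor, among the TGF-beta and BMP genes. HEYL had a log2 difference of 0.89. The median was lower for cholesterol synthesis genes (-0.10, percentile 0.34), NF-kB-induced genes (-0.08, percentile 1.21) and unfolded protein and amino acid response genes (-0.06, percentile 1.07), but with normexp correction the last 2 lay inside the random range (percentiles 7.11 and 38.4, the last with a median of 0.00). Unfolded protein and amino acid response genes did so too with quantile normalization (2.76) and the mean over probes (4.50).

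**Figure D3:**
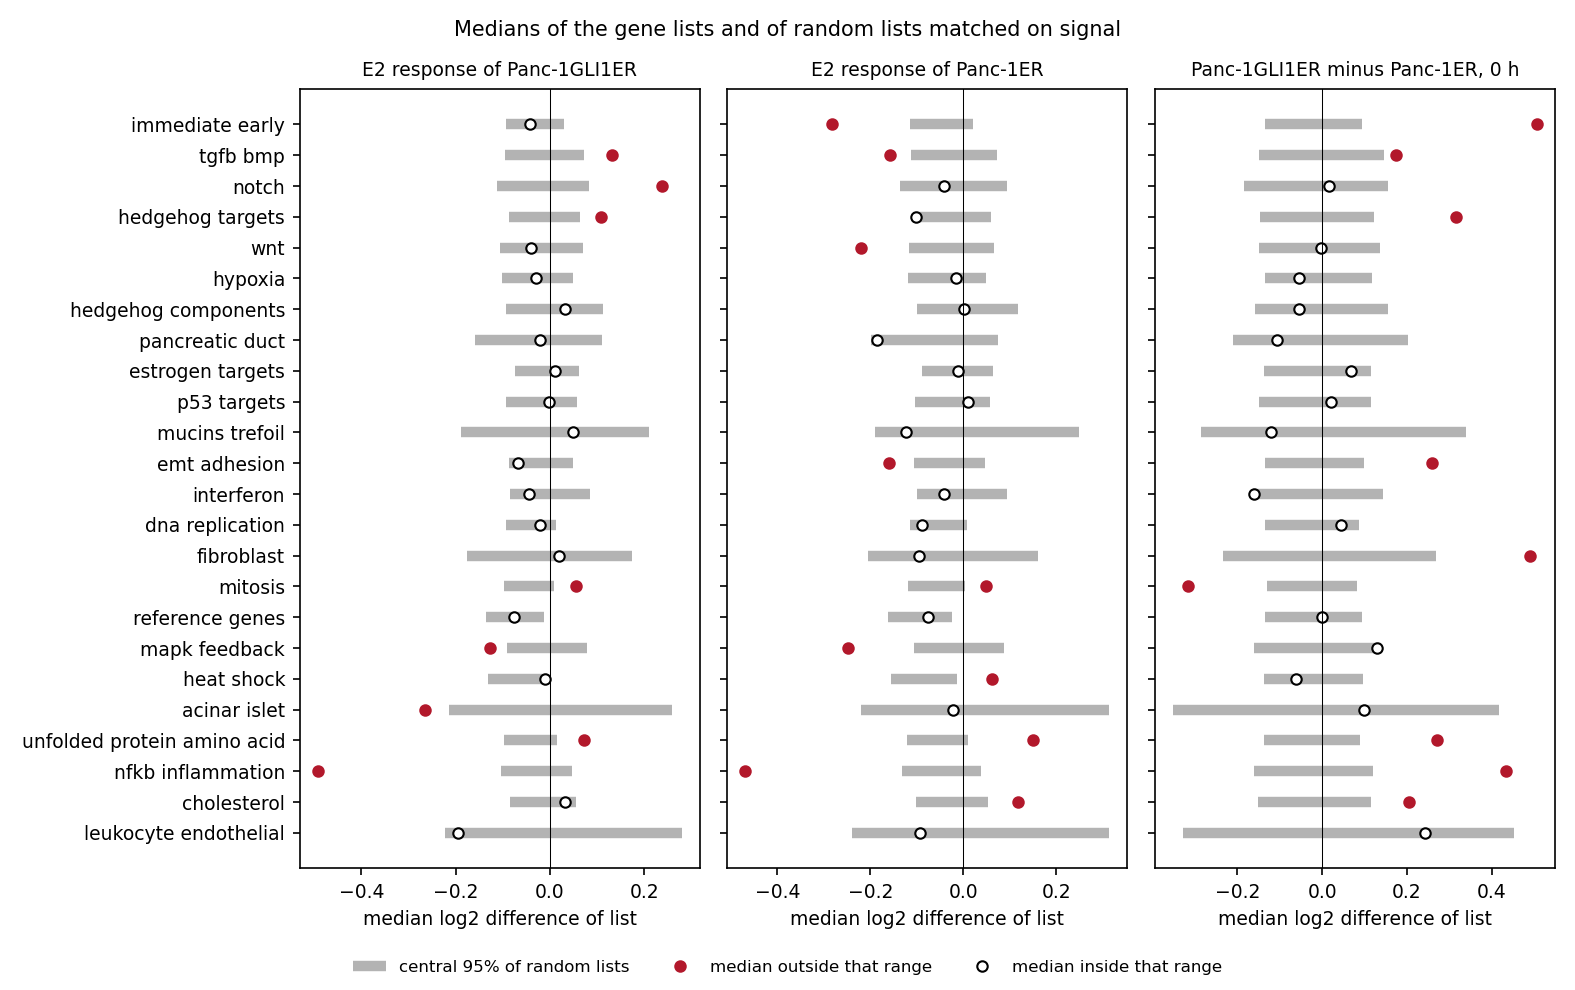
Median log2 difference of each of 24 gene lists (points) in the E2 response of Panc-1GLI1ER, the E2 response of Panc-1ER and the 0 h difference between lines, with the central 95% of matched random lists (grey bars) on a log2 axis; filled points lie outside that range. The NF-kB list lies at -0.49 and -0.47 in the responses and at 0.43 between lines at 0 h, and scaling to spike-in RNA instead would move each panel by the shift of all genes, to medians of all genes of -0.12, 0.21 and 0.20, so that medians near 0 change sign.

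The last comparison set both lines against each other before E2. EDN2 was 103-fold higher in Panc-1GLI1ER (log2 6.68, error 0.33), SULF2, a heparan sulfate sulfatase, 50.8-fold, KRT16 32.6-fold and SUSD4, a complement regulator, 25.6-fold. CP (ceruloplasmin, 18.4-fold), COL7A1, the collagen of anchoring fibrils (17.8-fold), AKR1C1, an aldo-keto reductase (16.8-fold), GLI1, PLXNA2, a semaphorin receptor (16.3-fold), and SUSD2 (16.2-fold) complete the 10 largest among genes measured on both arrays. In the other direction RHOH and CES1, a liver carboxylesterase, were each 7.53-fold lower, followed by FAM43B (6.25-fold, but log2 -0.29 on its other probe), ZC4H2, RBP7, a retinol-binding protein, TRPV2, a cation channel (5.43-fold), RNF157, TNFRSF1B, a TNF receptor, GAL, the neuropeptide galanin (4.39-fold), and CKMT1B, a mitochondrial creatine kinase. ARC, which rose after E2, was already 4.40-fold higher at 0 h, and KRT16 reached 108-fold at 3 h.

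Altogether 415 genes were higher and 239 lower by 2-fold or more in Panc-1GLI1ER at 0 h, and 416 and 215 at 3 h. The share of higher genes at 0 h was 63.5%, against 73.4% after normexp correction and 79.2% with spike-in scaling, which moved the median of all genes to 0.20. GLI targets were higher as a list (median 0.32, above all random lists). Here 7 members were higher by 2-fold, among them GLI1, ARC, KRT17 (at least 33.3-fold), IGFBP6 and IL1R2, and ABCG2, a drug efflux pump, was lower. NF-kB-induced genes (median 0.43) and immediate early genes (0.51) were above all random lists, with CXCL1 5.66-fold and CCL20 at least 11.7-fold higher. Adhesion and epithelial-mesenchymal transition genes had a median of 0.26, above all random lists, where CDH2 (N-cadherin, at least 2.44 in log2), FN1 (fibronectin), ZEB1, SNAI2 and the metalloproteinases MMP2, MMP7 and MMP9 were higher, CLDN3 was lower (log2 -1.27, but -0.38 on its other probe), and CDH1 had a log2 difference of -0.61. Fibroblast genes (median 0.49, percentile 99.8), including COL3A1 at 2.34 log2, unfolded protein and amino acid response genes (0.27), cholesterol synthesis genes (0.20) and TGF-beta and BMP genes (0.17) were higher. Mitosis genes were lower (median -0.32, below all random lists), with 23 of 27 members below 0 and CENPA, the centromeric histone, 2.12-fold lower. Each line lay on a slide of its own, so that line and slide cannot be told apart at 0 h or 3 h; the E2 responses were read within a slide.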

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

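In this part, the split of the probe test into higher and lower genes and the use of decreases shared by both lines were chosen only after the result was seen. The response of the TGF-beta and BMP list was above the random range in Panc-1GLI1ER and below it in Panc-1ER, a difference between groups of 0.289 in median log2 change that was not tested. The responses of 6 genes went in opposite directions by 2-fold or more in both lines, and these differences were not tested either, since each line has 1 array per time. MYORG, a glycosidase-like gene, differed by -3.423 log2 between lines, ADAMTS14, a metalloproteinase, by -2.901, ZNF441 by -4.154, RAPGEFL1 by -3.452, FAM78A by 3.373 and HORMAD2 by 2.904. In each of these 6 genes at least 1 of the 2 responses is a lower bound from an array on which the probe was dim. Among probes without a gene symbol, which no comparison uses, 35 had a response higher by 2-fold or more in Panc-1GLI1ER and 45 a lower one, out of 7370 measured.

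To weigh the error of single spots in the 2-fold responses of Panc-1GLI1ER, other probes were read: of 17 genes measured on both arrays that have another measured probe, 64.7% moved the same way by 1.5-fold or more on it. These included all 7 higher genes, among them RASD1, DEPP1, KRT16 and MFNG. This speaks against spot error for these 7 of 49 measured increases. The other increases had no other measured probe and were not checked. Of 10 lower genes, only 4 moved the same way by 1.5-fold or more on the other probe (CXCL2, HBEGF, GRIN1 and TRAF1). Of 48 lower genes, 27 also fell in Panc-1ER, on other arrays, against 0.213 expected. This argues against error that differs from array to array for these shared decreases. It cannot exclude an error tied to a probe, which could repeat in both lines. Of 7 shared decreases with another measured probe, only GRIN1 and TRAF1 were lower on it by 1.5-fold or more in both lines. Spot error stays open for the other decreases. Of 4 genes given as lower bounds with another probe above background on either array, 25% moved the same way by 1.5-fold or more on it (CLEC10A). GEN1, MYL4 and TSPOAP1 moved the other way on it, which leaves spot error open for the bounds. The share was 35.3% of 17 measured genes in Panc-1ER and 20% of 5 for the difference of responses, where SH3BP1 had -0.49 on its other probe. ARC and NOVA2 have no other measured probe in this test, and no biological explanation was tested here.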

How the results depend on the processing

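The setting that counts only genes measured on both sides was chosen only after the results had been seen; the others were fixed before the data were examined. The comparisons set single arrays against each other and involve no test; a fit of an E2 effect common to both lines, blocked by line, would leave 1 residual degree of freedom and was not run. Counts are given below as Panc-1GLI1ER higher and lower, Panc-1ER higher and lower, difference higher and lower, and 0 h higher and lower, where they moved by over 1.5 times. A 1.5-fold limit gave 294, 317, 295, 332, 140, 109, 903 and 647, larger by construction. Without a filter they were 314, 353, 269, 352, 481, 484, 732 and 514, as dim probes enter. Requiring all 4 arrays gave 44, 48, 27 and 48 for the responses and 234 and 154 at 0 h, and dropping the lower bounds gave 49, 52, 40, 52, 266 and 155, both by construction. With normexp correction Panc-1GLI1ER had 25 higher, Panc-1ER 22 higher and 66 lower, the difference 16 and 6, and 0 h 102 lower. With spike-in scaling Panc-1ER had 184 higher, the difference 15 and 75, and 0 h 156 lower, by the shift of all genes. The correlation of both responses was 0.6071 with normexp, 0.6235 with cyclic loess, 0.6212 with quantile normalization, 0.6157 with the mean over probes and 0.1433 without a filter; the cause was not tested. The GLI target median in Panc-1GLI1ER was 0.044 with normexp, 0.0086 with spike-ins, 0.1543 with the mean over probes and -0.0066 without a filter, and in Panc-1ER 0.1298 with spike-ins and 0.0862 without a filter. Signs turned with spike-in scaling, by its shift of all genes, for the difference of GLI targets (-0.1696), immediate early (-0.0595), TGF-beta and BMP (-0.0642), Wnt (-0.2304) and Notch genes (-0.1418), for mitosis (-0.0442) and unfolded protein response genes (-0.0289) in Panc-1GLI1ER, and for adhesion (0.0722), TGF-beta and BMP (0.0739) and Wnt genes (0.0114) in Panc-1ER. Normexp turned the difference of unfolded protein response genes (0.0012); the cause was not tested. Of 846 other list medians, 636 stayed within the spread of random lists, 199 moved and 11 turned. Of 1639 values of named genes, 1519 stayed within their technical error, 120 moved (70 with normexp, 26 with spike-ins) and 0 turned. Probes near background also limit the differences, as 48 of 61 genes at 2-fold lay in the lowest of 4 signal groups.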

Other observations

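Of the tests in this part, those of estrogen-induced genes, of other probes at 0 h and of genes lower in both lines, of the GLI target list without GLI1 and of stratified epithelial genes in each single response were chosen only after the result was seen. At 0 h Panc-1GLI1ER also differed in genes not named so far, all picked after their values had been seen. SNURF, an imprinted transcript, was at least 81.5-fold higher, IGFBP3, a binding protein of insulin-like growth factors, at least 46.1-fold (but log2 2.07 on its other probe) and CALD1, an actin-binding protein, at least 42.0-fold, and PRSS2, a trypsinogen of acinar cells, had a log2 difference of 1.78. SMO, the Hedgehog signal transducer, was lower by -1.23 log2 and IFIT1, an interferon-induced gene, by -1.48. Interferon genes had a median of -0.16 (percentile 2.74, but 1.72 with the mean over probes), MAPK feedback genes 0.13 (96.8, but 98.5 with normexp) and Notch genes 0.02 (64.1), inside the random range.

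Further lists stayed inside the random range in the E2 responses of Panc-1GLI1ER and Panc-1ER. Medians were -0.02 and -0.09 for DNA replication genes, -0.03 and -0.01 for hypoxia genes, -0.00 and 0.01 for p53 targets although BTG2 rose in Panc-1GLI1ER, -0.04 and -0.04 for interferon genes (percentile 2.02 in Panc-1GLI1ER with normexp), 0.03 and 0.00 for Hedgehog pathway components although SHH fell in both, 0.05 and -0.12 for mucins and trefoil factors, -0.02 and -0.19 for pancreatic duct genes, 0.02 and -0.10 for fibroblast genes, and -0.20 and -0.09 for leukocyte and endothelial genes. FOXA2, a pioneer factor of endoderm, had log2 changes of 0.93 and 0.10, and SLPI, a protease inhibitor, fell in Panc-1ER (-1.18) with -0.20 in Panc-1GLI1ER. Reference genes had -0.08 and -0.07.

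The likeness of both E2 responses was weighed against technical and biological causes. Signal-dependent scaling is excluded as the main cause, since the correlation was 0.624 after cyclic loess. Known estrogen-induced genes had percentile 53.3 in Panc-1ER, inside the random range, which leaves induction through them open. Of 7 genes that fell in both lines and have another measured probe, 28.6% were lower on it by 1.5-fold or more in both lines (GRIN1 and TRAF1). This leaves a difference of single probes between early and late arrays open as well.

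The higher expression at 0 h could come from activity of the GLI1 fusion before E2. GLI targets without GLI1 had a median of 0.294 (percentile 99.98), which may fit such activity, but NF-kB, immediate early and adhesion genes were high too, so it is not specific to them. The 36 genes with a higher response had a median 0 h difference of -0.075 (percentile 8.49), below the middle, which the prediction written beforehand counted against the explanation; the limit was changed after the result was seen to the central 95% of random lists, which leaves it open. Selection on a high response favours low 0 h values, and the mirror set of 25 genes had 0.721. On other probes 88.0% of 83 genes differed the same way by 1.5-fold or more, which argues against single probes of a slide as the main cause for genes with another probe. Both probes of a gene lay on the same slide, so an effect of the whole slide was not tested. The test of other probes replaced an earlier one on the spread of spike-ins after the result was seen.

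Hypotheses were tried from single genes, each tested on members that had not prompted it. AKR1C1, AKR1C3 and ALDH3A1 pointed to NRF2 targets, which had a 0 h median of -0.253 (percentile 0.02) over 16 members, against the hypothesis of a higher NRF2 programme. KRT16, KRT17, PI3, DEFB4A, ELF3 and SLPI pointed to a stratified epithelial programme that responds to E2 in Panc-1GLI1ER. The median difference of responses was -0.015 (percentile 30.9) over 15 members, below the middle, which the prediction written beforehand counted against the programme. The median lay inside the random range, however, so by the limit changed above for activity before E2 the difference alone would not decide. In the Panc-1GLI1ER response itself the list had -0.13 (percentile 0.965) over 19 members and in Panc-1ER -0.18 (percentile 0.255), both below the random range, which is against an induced programme. At 0 h the same list had a median of 0.37, above all random lists, with KRT4 and S100A2 at 1.33 and 1.69.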
